A study of Mus musculus with 145 samples.

How the data were processed

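Genomic DNA of 94 untreated and 51 treated mouse mammary tumours was examined by transposon insertion mapping. The mice carried a Cre gene under the WAP promoter, which is active in the mammary gland from late pregnancy, together with a Cre-dependent piggyBac transposase, a Cre-dependent PIK3CA H1047R gene and the transposon donor ATP1. Per the labels' protocols, sheared DNA was ligated to a splinkerette adaptor, fragments that held the 5' arm of the transposon were amplified and barcoded per tumour, and 4 library pools were sequenced on an Illumina HiSeq 2500 with paired reads of 100 bp. The genome build was mm10 per the submitters' processing notes, and the aligner, the site caller and its filters were not given in the sources used here. The series title names ATAC-seq, whereas its design text and protocols describe transposon integration mapping, and the values were treated as the latter.

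The deposited site table gave each of 198107 sites a chromosome, position, strand and sequence context, and gave each library a read count per site as a whole number, which the authors did not scale or normalise, as far as the values show. Of these sites, 11732 had 0 reads in every library. A further deposited column per library, of another kind, held a whole number per site that was never above the read count and that the file headers do not define, so it was used only in alternatives. A table of the authors gave 24036 regions (13391 gene regions and 10645 intergenic regions), each with the number of insertions and of hit tumours per group. In that table the authors also gave the percent of tumours of each group with an insertion in the region. Per the file headers, the same table held a signed −log10 p-value score of a gene-centred common integration site test for each group, whose method was not given in the sources used here. Gene symbols were taken from the identifier of each gene region, since the symbol column of that table matched the symbol of the identifier in 0 of 2901 regions that had both. The identifiers of 12384 gene regions were found in the RefSeq gene table, and positions were printed only as the deposited tables gave them. No genome sequence or gene model was used, so exons and introns were not assigned, and the strand of a gene was inferred from which end of its region had been extended. Shares of same-strand insertions under this inference lay within 25 percentage points of the authors' shares in 97.2% of 1705 genes, against 75.1% with the strands flipped.

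Groups were taken from the treatment labels, and the mouse of each tumour from its title. The titles named 48 mice, whereas the labels state 53 for the study. Titles had 4 forms, TgTum (61 tumours) and tgTum (33) in the untreated group and Tgtumor (35) and Mouse (16) in the resistant group, so that no form held both groups. Library totals ran from 51 to 1604365 reads, with a median of 63285. One untreated library had the suffix R2 in its title and the mouse and gland of another library. It shared 8 of 85 top sites with that partner (9.41%), 13 of 4371 pairs of untreated libraries shared a larger percent, and by the rule fixed beforehand the libraries were kept as separate tumours, so that n was 94 rather than 93 in the untreated group. The highest percent shared by an untreated pair was 67%, and the libraries of that pair were also counted as separate tumours. Untreated library 79 listed 1003 sites, of which 40 stayed its own after shared positions were dropped or given to the tumour with the most reads there.

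The designs below were fixed before the data were examined. For each tumour the 100 sites with the most reads formed its integration set, or all sites where it had fewer (15 tumours). A position and strand with reads in several tumours was kept only in the tumour with the most reads there, and 16 sites with reads in the majority of libraries were dropped. Reads were not scaled for depth in this rule, so it can favour the deeper libraries, which were those of the resistant group. Resistant libraries kept a mean of 1490 of 1738 listed sites and untreated libraries 1174 of 1542. Medians ran the other way, at 740 kept and 1042 listed against 869.5 and 1109.5. The sets held 13501 sites, of which 48.3% lay inside a gene region. A tumour counted as hit in a gene when at least 1 site of its set lay in the gene region of the authors' table. Shares of tumours were compared by a two-sided Fisher exact test, with Benjamini-Hochberg adjustment over the genes hit in at least 5 tumours and a threshold of 0.05, and were given with Clopper-Pearson 95% intervals. These intervals cover counting of tumours only, since PCR reads without molecular identifiers are not independent molecules. Tumours of one mouse are not independent either, so labels were also permuted over mice with 100000 resamples, on the share of tumours hit. Untreated mice gave more tumours each than resistant mice. In the simulation given below that permutation was too lenient at low shares, and unequal numbers of tumours per mouse were not tested as the cause. Because of this leniency, mean shares per mouse were added after the data were seen.

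Recurrence within a group was tested by a one-sided exact Poisson-binomial test against each gene's share of chromosome length and each tumour's number of sites, for genes hit in at least 3 tumours of the group, over which p was adjusted. That choice selects on the tested quantity, so adjustment over every gene region was added after the data were seen. With simulated sites placed evenly, 2 of 54 and 6 of 188 such genes passed in the resistant and untreated groups, and 0 passed over every region. Chromosome 10, which had the largest excess of sites over its length, was taken as the donor chromosome and left out there. The expectation from TTAA positions that had been planned was not run, because it needs the genome sequence. Orientation in named genes was tested by an exact binomial test per group and a Fisher exact test between groups. The 14 gene lists fixed beforehand covered RAS-MAPK brakes and activators, PI3K-AKT-mTOR brakes and activators, receptor tyrosine kinases, cell cycle and p53, chromatin regulators, mammary lineage transcription factors, NOTCH with WNT and Hippo, NRF2 and redox, adhesion and polarity, TGF-beta and SMAD, marker genes of other cells of the gland, and long genes as a length control. They were compared by the share of tumours with any list gene hit, permuted over mice and adjusted over the lists. Named genes were chosen by a rule: Nf1, the genes past the threshold between groups or else those with the smallest p until 20 were reached, the 10 genes outside chromosome 10 hit in the most tumours of each group, and the 2 members of each list hit in the most tumours. This rule gave 52 genes, of which some are not reported here.

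Alternatives covered the number of sites per tumour, a minimum of 10 reads or of 0.1% of reads per site, shared positions kept, 10 kb flanks, the mouse as the unit, the number of sites as a covariate, other minimum hits, and subsets by title form. Others were added after the data were seen and are named as such with their results. The statistics were tested on simulated data first. In simulated comparisons of 51 with 94 tumours, in which 447 genes were tested, 49.3% of genes raised by 10 percentage points in the resistant group were called, 98.5% of those raised by 20 and 100% of those raised by 30, with 0 calls among 260 unchanged genes. The simulation drew tumours independently. It also raised 67, 66 and 67 genes at once, which loosens the adjustment, so these rates are too high where few genes differ. In the real comparison Kmt2c differed by 21.1 percentage points with an adjusted Fisher exact p of 0.157. With no difference between groups, the permutation over mice gave an unadjusted p under 0.05 in 6.25% of 400 simulated tests at shares around 25% and in 10% at shares around 2%. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.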

Results

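Transposon insertion sites were mapped in mammary tumours driven by PIK3CA H1047R, an activating mutant of the catalytic subunit of PI3K alpha, in mice whose mammary cells also expressed the piggyBac transposase. The ATP1 transposon inserts at TTAA and, depending on its position and orientation, can activate or truncate the gene in which it lands. The comparison asked which genes were hit more often in tumours that grew under BYL719 (alpelisib), an inhibitor of PI3K alpha, than in untreated tumours. Untreated tumours numbered 94 by library, from 23 mice. They numbered 93 if the libraries that share a mouse and gland are a single tumour. The other 51 tumours, from 25 mice, had reached 250 mm3, received 30 mg/kg BYL719 daily and grown over at least 3 consecutive measurements in 3 weeks, and these are called resistant. In all, 186375 sites had reads in at least 1 library, 84.7% of the deposited sites lay at TTAA, and chromosome 10 held 18.1% of sites against 4.8% of chromosome length. Libraries held a median of 136932 reads in the resistant group and 48339 in the untreated group, a 2.76-fold difference of geometric means (permutation over mice, p = 0.00062). By title form the medians were 56672 (TgTum) and 22542 (tgTum) in untreated tumours, and 129250 (Tgtumor) and 237224.5 (Mouse) in resistant tumours.

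The number of integration sites per tumour did not differ detectably between the groups. Resistant tumours listed a median of 1042 sites and untreated tumours 1109.5 (mean log10 number 3.00 ± 0.469, SD, n = 51, and 3.02 ± 0.415, n = 94, permutation over mice, p = 0.888). Counting only sites with at least 100 reads, the medians were 113 and 85. The ratio of geometric means was 1.99 (p = 0.0527), with 7 libraries of 0 such sites, 1 of them resistant, counted as 1. Without these libraries, left out after the data were seen, it was 1.67 (p = 0.0845). Title forms within a group differed more than the groups did, with medians of 1706 (TgTum), 525 (tgTum), 1520 (Tgtumor) and 465 (Mouse) listed sites.

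**Figure D1:**
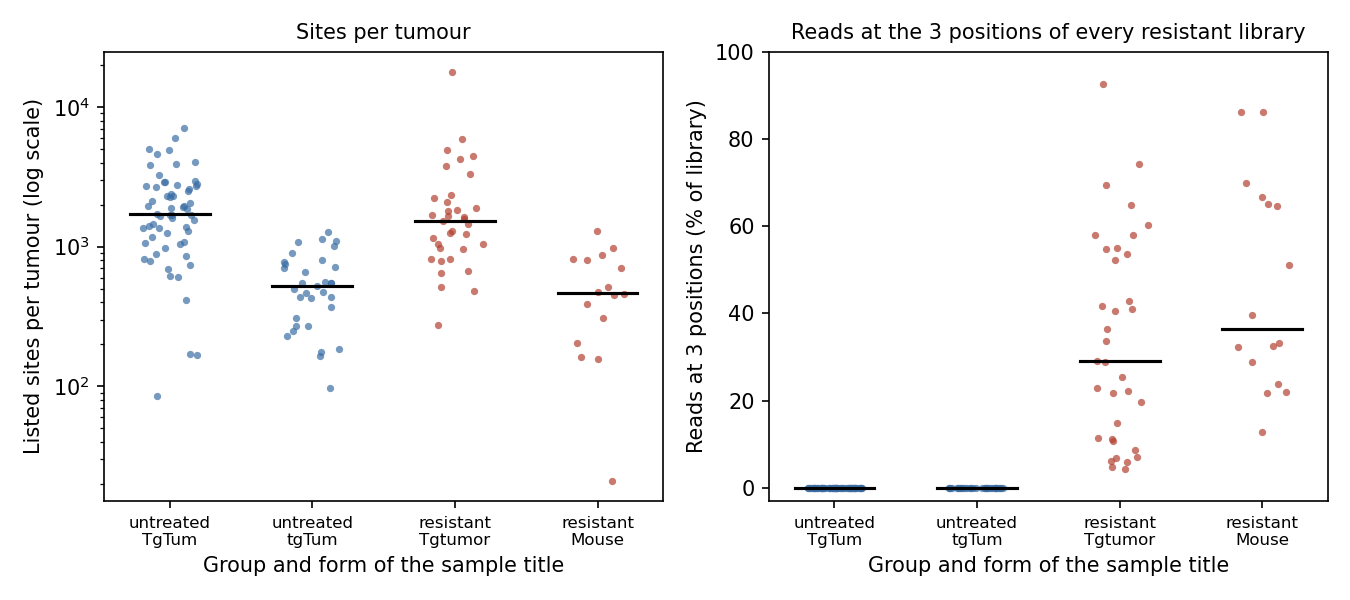
Listed sites per tumour on a log scale (left) and percent of reads at 3 positions that every resistant library listed (right), by group and title form. Each point is a tumour and black lines are medians, which were 1706, 525, 1520 and 465 listed sites from left to right, and the 3 positions had reads in the resistant libraries alone.

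Nf1, which encodes neurofibromin, a GTPase-activating protein that switches RAS off, was hit in 6 of 51 resistant tumours (11.8%, 95% interval 4.44 to 23.9) and in 3 of 94 untreated tumours (3.19%, 0.663 to 9.05). The series title names loss of this gene. With 100 sites per tumour the odds ratio was 4.0 (95% interval 0.811 to 25.9) and did not pass the test (Fisher exact test, p = 0.0668, adjusted p = 1 over 199 genes and 0.0668 adjusted over the list alone, in which it was the one RAS-MAPK brake tested). With 300 sites per tumour Nf1 was hit in 14 resistant tumours (27.5%) and 6 untreated tumours (6.38%), and with every site of at least 10 reads in 18 (35.3%, 22.4 to 49.9) and 8 (8.51%, 3.75 to 16.1). Those differences had Fisher exact p = 0.000789 and p = 0.000164, with adjusted p = 0.324 over 822 genes and 0.419 over 2558 genes. Counted over mice, Nf1 was hit in 13 of 25 resistant and 5 of 23 untreated mice with 300 sites (Fisher exact p = 0.0401), in 15 and 6 mice with at least 10 reads (p = 0.0229), and in 5 and 2 mice with 100 sites (p = 0.419), the wider sets over mice having been added after the data were seen. With 100 sites the planned permutation over mice on the share of tumours gave p = 0.0786. Mean shares per mouse, added later, were then 14% and 2.83% (permutation p = 0.1085). The Nf1 region spanned positions 79337892 to 79581609 of chromosome 11 (mm10, plus strand inferred, identifier 18015). In resistant tumour 8 the 2 sites with the most reads both lay in Nf1, at 79378016 (11401 reads) and 79364071 (7348 reads), and in untreated tumour 87 the site with the most reads did, at 79366009 (2521 reads). Resistant tumour 10, from the same mouse as tumour 8, carried 8 separate Nf1 positions. Among resistant tumours, Nf1 was hit in 14.3% of the Tgtumor form and 6.25% of the Mouse form with 100 sites, and among untreated tumours in 1.64% of the TgTum form and 6.06% of the tgTum form. With every site of at least 10 reads these shares were 42.9%, 18.8%, 8.2% and 9.09%. Mouse tumours held fewer such sites than Tgtumor tumours (median 253.5 against 673).

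**Figure D2:**
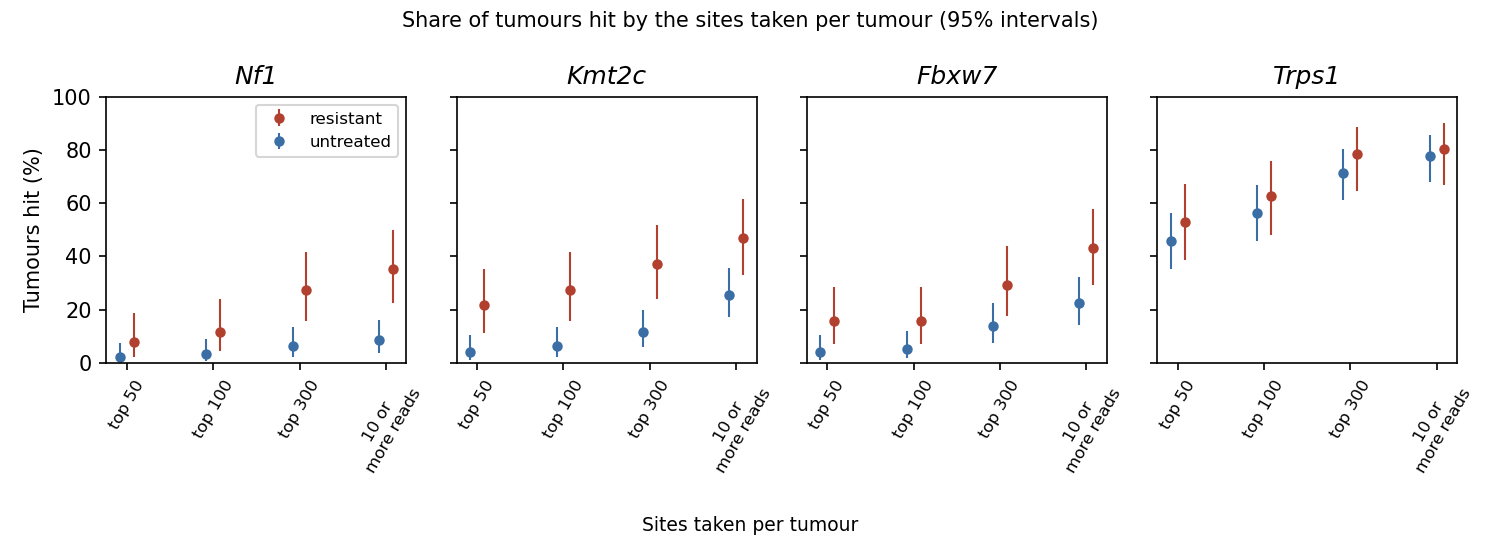
Percent of tumours hit in Nf1, Kmt2c, Fbxw7 and Trps1 (vertical axis) by the sites taken per tumour (horizontal axis), in 51 resistant (red) and 94 untreated (blue) tumours, with Clopper-Pearson 95% intervals. Nf1 went from 11.8% and 3.19% with 100 sites to 35.3% and 8.51% with every site of at least 10 reads, whereas Trps1 was hit in over 50% of resistant tumours in each set.

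Kmt2c, a histone H3 lysine 4 methyltransferase and a tumour suppressor of the breast, had the smallest p of all genes. It was hit in 14 of 51 resistant tumours (27.5%, 95% interval 15.9 to 41.7) from 11 mice and in 6 of 94 untreated tumours (6.38%, 2.38 to 13.4) from 6 mice, an odds ratio of 5.48 (1.81 to 18.8, Fisher exact test, p = 0.000789, adjusted p = 0.157, and 0.00158 adjusted over the list alone of chromatin regulators). With the same sets, the planned permutation over mice on the share of tumours gave Kmt2c an unadjusted p of 0.00128 (adjusted p = 0.255). Mice with at least 1 hit tumour (Fisher exact p = 0.237) and mean shares per mouse, added later (29% and 11%, permutation p = 0.0637), did not differ detectably. Ctnnd2, which encodes delta-catenin, was hit in 5 resistant tumours (9.80%) and 1 untreated tumour (1.06%, p = 0.0205). Fbxw7, the substrate receptor of a ubiquitin ligase for cyclin E, MYC and NOTCH, was hit in 8 resistant tumours (15.7%, 7.02 to 28.6) and 5 untreated tumours (5.32%, 1.75 to 12, p = 0.0636). Ank3, which encodes ankyrin G, was hit in 8 and 5 tumours (p = 0.0636). Zbtb20, a zinc finger repressor, was hit in 8 and 6 (p = 0.0828). Tnik, a kinase of WNT signalling, Plxdc2 and Cep112 were each hit in 4 resistant tumours and 1 untreated tumour (p = 0.0519). By the Fisher exact test with Benjamini-Hochberg adjustment 0 of 199 genes passed the threshold and 2 had an unadjusted p under 0.05, Kmt2c and Ctnnd2. The Kmt2c region spanned positions 25271794 to 25500783 of chromosome 5 (minus strand inferred, identifier 231051). Kmt2c was hit in 34.3% of Tgtumor and 12.5% of Mouse tumours with 100 sites (Fisher exact p = 0.176), and in 60% and 18.8% with every site of at least 10 reads (p = 0.00761). These forms had 5 mice in common, which this test ignores, and Mouse tumours held fewer sites of at least 10 reads (median 253.5 against 673). Kmt2c passed the adjusted threshold with the Tgtumor form alone, with genes hit in at least 10 tumours and with shared positions kept (adjusted p from 0.0243 to 1 over its alternatives). Over mice with at least 10 reads it was hit in 15 of 25 resistant and 17 of 23 untreated mice (p = 0.369), a count raised in untreated mice by their larger number of tumours each. Mean shares per mouse were 41.3% and 35.1% with these sites (permutation p = 0.560), and 35.3% and 16.9% with 300 sites (p = 0.0591).

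**Figure D3:**
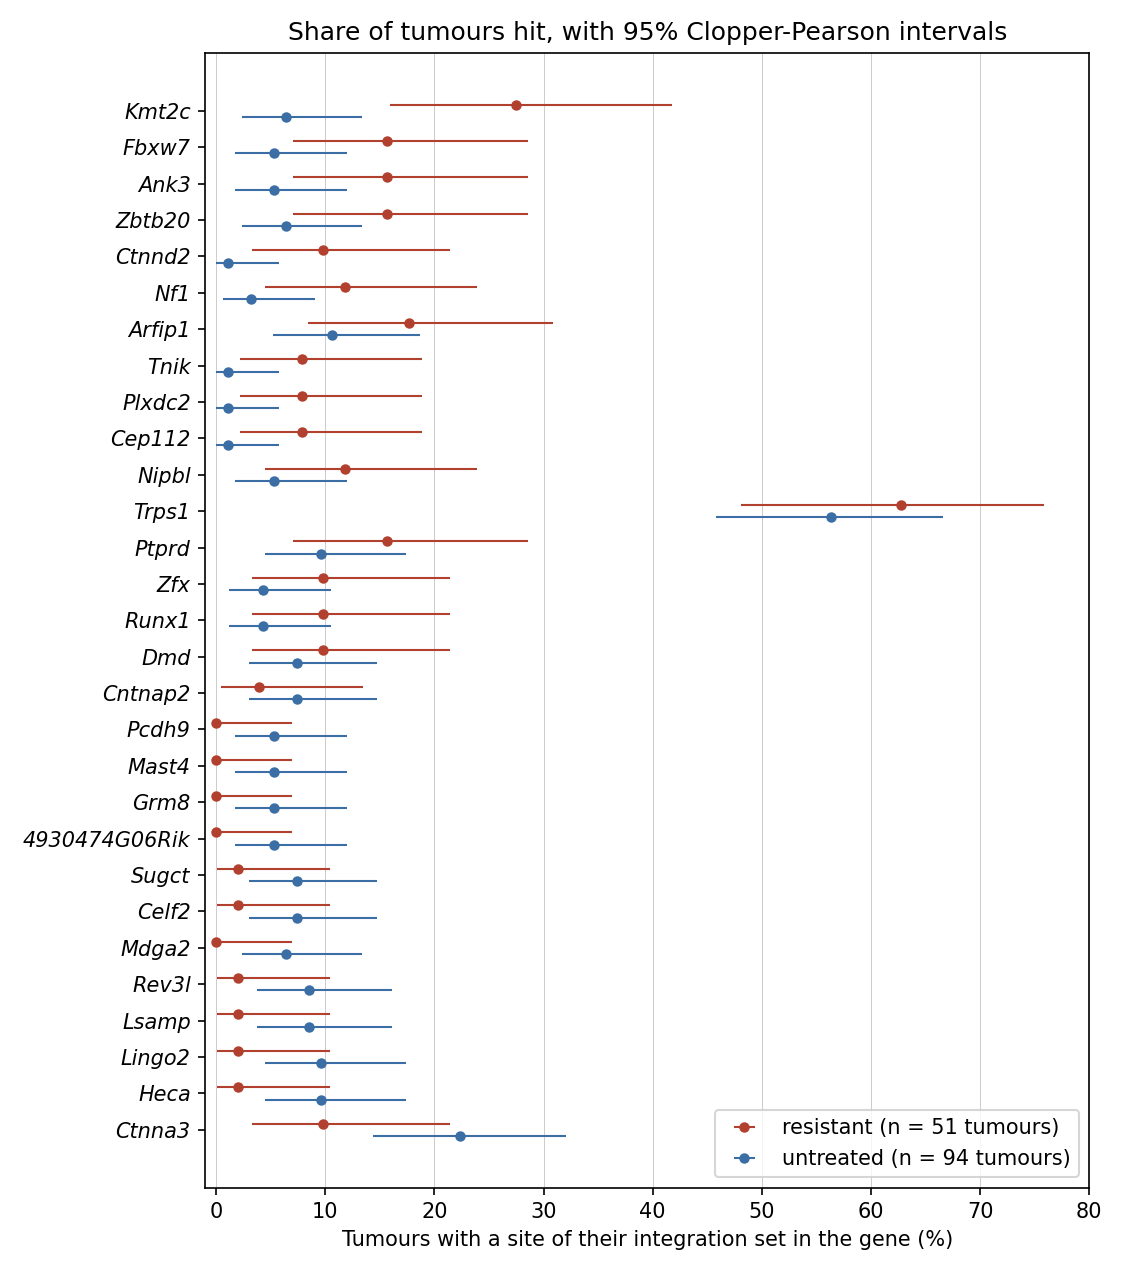
Percent of tumours with a site of their integration set in each gene (horizontal axis) for most of the genes named by the comparison or hit in the most tumours, in 51 resistant (red) and 94 untreated (blue) tumours, with Clopper-Pearson 95% intervals. Kmt2c stood at 27.5% and 6.38%, and Trps1 was hit most in both groups, at 62.7% and 56.4%.

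Of the 20 genes named by the comparison between groups, 11 had a lower share in resistant tumours, and these were hit in at most 5 resistant tumours each. Ctnna3, which encodes alpha-T-catenin and lies on chromosome 10, was hit in 5 resistant tumours (9.80%, 95% interval 3.26 to 21.4) and 21 untreated tumours (22.3%, 14.4 to 32.1, Fisher exact p = 0.0715). Chromosome 10 held a median of 21% of a resistant set and 25.5% of an untreated set (permutation over mice, p = 0.175). Lingo2 and Heca were hit in 1 and 9 tumours each (p = 0.0993), and Lsamp and Rev3l, the catalytic subunit of DNA polymerase zeta, in 1 and 8 each (p = 0.160). Mdga2 was hit in 0 resistant tumours (upper 95% bound 6.98%) and 6 untreated tumours (p = 0.0906). Grm8, Mast4, Pcdh9 and 4930474G06Rik were hit in 0 and 5 tumours each (p = 0.162). Heca and Rev3l also lie on chromosome 10, as does Ank3 among the genes with a higher share. Regions of these genes ran from 50 kb (Heca) to 2194 kb (Lsamp). Those of the 9 genes with a higher share ran from 166 kb (Fbxw7) to 859 kb (Ctnnd2). With every site of at least 0.1% of the reads Ctnna3 passed the threshold as lower in resistant tumours (adjusted p = 0.00175, from 0.00175 to 1 over its alternatives), at a difference of -37.0 percentage points. Once reads at 3 positions that all resistant libraries listed were left out of the totals, the difference was -25.2 percentage points and did not pass (unadjusted p = 0.0039, adjusted p = 0.802 over 603 rather than 534 genes).

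Recurrence was tested only for genes hit in at least 3 tumours of a group, which selects on the tested quantity, so the adjusted p values of that test are too favourable. Trps1, a GATA-type repressor of mammary epithelial cells, was hit far more often than its length predicted in both groups, in 32 of 51 resistant tumours (62.7%, 95% interval 48.1 to 75.9, 94.5-fold over expectation, exact Poisson-binomial test, adjusted p = 2.61e-55) and 53 of 94 untreated tumours (56.4%, 45.8 to 66.6, 88.5-fold, adjusted p = 1.2e-88). Its share did not differ detectably between the groups (Fisher exact p = 0.485). In resistant tumours Kmt2c (42.9-fold), Fbxw7 (33.8-fold), Zfx, a zinc finger transcription factor of the X chromosome (5 tumours, 68.8-fold), Nipbl, the cohesin loader (6 tumours, 23.7-fold), Nf1 (17.3-fold, adjusted p = 1.53e-05), Runx1, a transcription factor mutated in breast cancer (5 tumours, 15.5-fold), and Zbtb20 (6.63-fold) followed. In untreated tumours Pisd-ps3 (5 tumours, 45.2-fold), Zfx (31.1-fold), Tnrc6c, a component of microRNA silencing (5 tumours, 17.8-fold), followed, then Kmt2c (10.4-fold), Fbxw7 (12-fold), Nipbl (11.2-fold) and Vgll4, an antagonist of YAP at TEAD factors (4 tumours, 14.5-fold). Pisd-ps3 is a pseudogene. Nf1 in untreated tumours (3 tumours, 4.88-fold) did not pass (adjusted p = 0.0594). In all, 45 of 67 tested genes passed in resistant tumours and 59 of 202 in untreated tumours. Of the 33 genes tested in both groups, 11 passed in both. With adjustment over all 12557 gene regions outside chromosome 10, added after the data were seen, 8 passed in resistant tumours and 4 in untreated tumours, 2 of them in both. The 8 were Trps1, Kmt2c, Fbxw7, Zfx, Nipbl, Nf1 (adjusted p = 0.00286), Runx1 (0.0335) and Zbtb20 (0.0385). The 4 were Trps1, Pisd-ps3, Zfx and Tnrc6c (adjusted p = 0.0327), whereas Kmt2c (0.0688), Fbxw7 (0.143), Nipbl (0.169) and Vgll4 (0.286) in untreated tumours did not pass. The expectation took length alone, and piggyBac also favours open chromatin. The test also treats tumours of one mouse as independent. Resistant hits came from 5 mice for Nf1 (6 tumours) and from 4 mice each for Zfx and Runx1 (5 tumours each). Those of Nipbl (6) and Zbtb20 (8) came from as many mice as tumours. Over genes hit in at least 3 tumours, 24 and 30 passed with 50 sites per tumour, and 225 and 389 with every site of at least 10 reads.

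**Figure D4:**
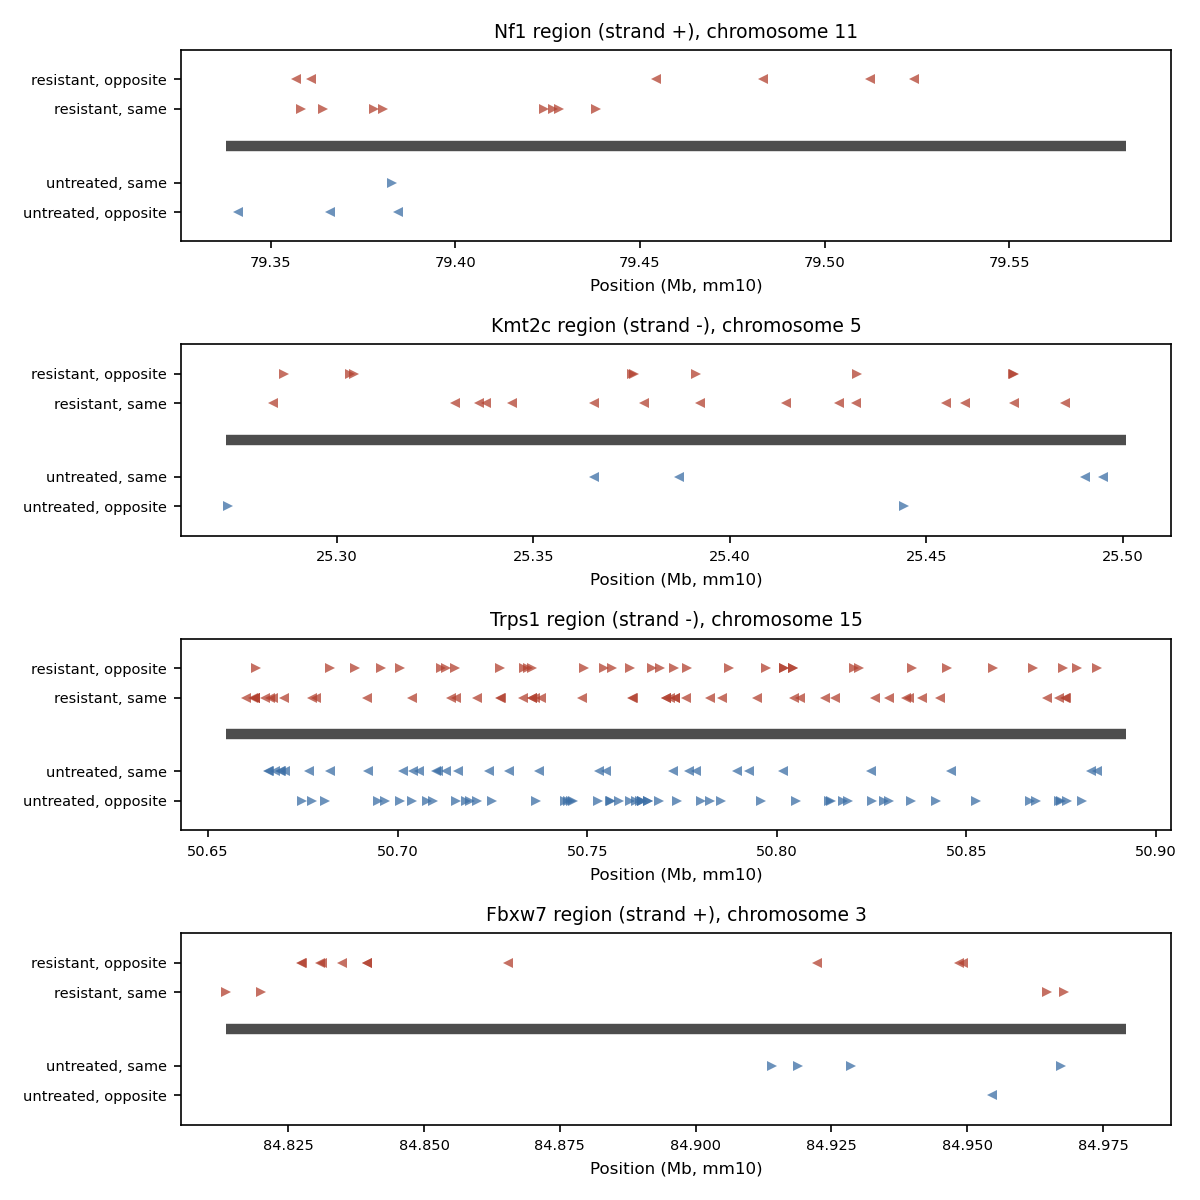
Insertion positions in the regions of Nf1, Kmt2c, Trps1 and Fbxw7 along mm10 (horizontal axis, Mb), above the gene bar for resistant (red) and below it for untreated (blue) tumours, by orientation relative to the gene. Each triangle is a site of an integration set and points along the transposon, and Trps1 sites were spread over the whole region with 84 sites in each group.

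Sites in Trps1, Nf1, Kmt2c and Fbxw7 lay in both orientations. Neighbouring positions were counted apart here, and resistant Trps1 sites numbered 82 with those of a tumour within 10 bp counted once. In Trps1, 49 of 84 resistant sites and 31 of 84 untreated sites had the orientation of the gene (exact binomial p = 0.156 and p = 0.0214), and the groups differed at Fisher exact p = 0.00844, adjusted p = 0.312 over 37 genes. Nf1 held 8 sites in the orientation of the gene and 6 against it in resistant tumours, Kmt2c 15 and 9, and Fbxw7 4 and 11 (exact binomial p = 0.791, 0.308 and 0.118). Adjusted by Benjamini-Hochberg, 0 of 88 exact binomial tests and 0 of 37 Fisher exact tests passed, with 3 and 3 at an unadjusted p under 0.05.

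Of the 14 gene lists 0 differed between the groups after adjustment, and 1 had an unadjusted p under 0.05 in the permutation over mice. NOTCH, WNT and Hippo genes were hit in 29.4% of resistant tumours (95% interval 17.5 to 43.8) and 16% of untreated tumours (9.21 to 24.9, p = 0.0394, adjusted p = 0.450). Of the 8 members hit, 7 had a higher share in resistant tumours, among them Fbxw7, Lats1, a kinase that restrains YAP (3 tumours in each group), and Nf2, which encodes merlin (2 and 0). Lats1 lies on the donor chromosome, 10, as does Rspo3, the member with a lower share (1 and 4 tumours). RAS-MAPK brakes were hit in 19.6% and 9.57% (p = 0.0993, adjusted p = 0.450), with 3 of 6 hit members higher in resistant tumours, and Rasa1, a RAS GTPase-activating protein, was hit in 1 and 2 tumours. With 300 sites per tumour the RAS-MAPK brakes passed the threshold, at a difference of 24.2 percentage points (adjusted p = 0.0084, from 0.0084 to 1 over the alternatives). Nf1 alone was then hit in 14 and 6 tumours, a difference of 21.1 percentage points, and Rasa1 in 6 and 3 tumours. Chromatin regulators were hit in 31.4% and 19.1% (adjusted p = 0.450), with 4 of 9 hit members higher, and Kdm6a, a histone H3 lysine 27 demethylase, was hit in 3 and 3 tumours. Of the members tested, 1 (Kmt2c) passed adjusted over the list alone and 0 passed over all genes.

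Genes of the inhibited pathway itself were hit at similar shares. PI3K-AKT-mTOR brakes were hit in 9.80% of resistant and 9.57% of untreated tumours (adjusted p = 0.970), among them Inpp4b, a phosphoinositide phosphatase, in 1 and 5 tumours. The activators of that pathway were hit in 5.88% and 6.38% (adjusted p = 0.967), with Sgk1 in 0 resistant tumours and in 4 of the 6 untreated tumours hit. Sgk1 lies on the donor chromosome, 10, as do Lats1 and Rspo3 above and Txnrd1, Ptprk and Dcn below. The list tests did not leave that chromosome out. RAS-MAPK activators were hit in 7.84% and 3.19% (adjusted p = 0.450), with Sos2, an exchange factor of RAS, in 2 and 0 tumours. Receptor tyrosine kinases were hit in 13.7% and 7.45% (adjusted p = 0.450), with Erbb4 in 3 and 5 and Ntrk3 in 1 and 1. Mammary lineage transcription factors were hit in 29.4% and 27.7% (adjusted p = 0.941), with Esr1, the estrogen receptor gene on chromosome 10, in 7 and 18 tumours and Runx1 in 5 and 4. Cell cycle and p53 genes were hit in 5.88% and 2.13% (adjusted p = 0.450, Ccnd3 in 1 and 0, Cdkn2a in 0 and 1). NRF2 and redox genes were hit in 3.92% and 1.06% (adjusted p = 0.450, Cul3, the ligase partner of KEAP1, in 2 and 0, Txnrd1 in 0 and 1). Adhesion and polarity genes were hit in 31.4% and 25.5% (adjusted p = 0.685, Ptprk in 8 and 11, Pard3b in 5 and 6). TGF-beta and SMAD genes were hit in 5.88% and 7.45% (adjusted p = 0.937, Tgfbr2 in 1 and 2, Smad2 in 0 and 2). Marker genes of other cells of the gland were hit in 2.0% and 1.1% (adjusted p = 0.685, Vwf in 1 and 0, Dcn in 0 and 1). The long genes were hit in 51.0% and 63.8% (adjusted p = 0.450, Ptprd in 8 and 9, Dmd in 5 and 7).

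The authors' deposited table, which counts insertions by rules of its own, gave Nf1 in 56.9% of resistant and 31.9% of untreated tumours, with signed −log10 p scores of 27.7 and 1.5. In the authors' deposited table Kmt2c stood at 82.4% and 48.9% (scores 68.9 and 12.3), Fbxw7 at 60.8% and 36.2% (scores 47 and 9.33) and Trps1 at 96.1% and 95.7%. The largest differences in the authors' deposited table, chosen here after their values were seen, were those of Cradd, a death-domain adaptor (100% and 18.1%), Sox6, a transcription factor (100% and 28.7%), and Kalrn, a guanine nucleotide exchange factor (88.2% and 19.1%). Spred1, a RAS-MAPK brake, followed among the 20 largest in the authors' deposited table (62.7% and 11.7%), with 13 insertions over 32 resistant tumours. In the integration sets, which hold fewer sites per tumour and keep each position in 1 tumour, Spred1 was hit in 1 resistant and 2 untreated tumours and Nf1 in 6 and 3.

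Part of each resistant library came from 3 positions that all 51 resistant libraries and 0 of 94 untreated libraries listed. These lay at 115706530 of chromosome 7 in the Sox6 region (minus strand), at 95288284 of chromosome 10 in the Cradd region (plus strand) and at 67017939 of chromosome 11 outside any gene region (minus strand). Together they took a median of 33.2% of the reads of a resistant library, from 4.47% to 92.5%.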

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

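The tests of cross-talk, of one DNA source, of inherited transposons, of other groupings of the mice and of one position read in many tumours were chosen after the result they measure was seen, and the others before.

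A strong signal lay at 3 positions that carried reads in all 51 resistant libraries and in 0 untreated ones, in Sox6, a transcription factor gene, in Cradd, a death-domain adaptor gene, and on chromosome 11 outside any gene region, which together took a median of 33.2% of a resistant library's reads. Selection for insertions in Sox6 and Cradd is argued against as the source of this signal, since 97.5% and 97.8% of the resistant reads in Sox6 and Cradd sat at the single shared position, whereas the top position held 9.3% of reads in Trps1, 39% in Nf1, 46.4% in Fbxw7 and 50.3% in Kmt2c. These positions took medians of 13.05% and 9.87% of a resistant library, so such high shares largely follow, and weaker selection elsewhere in these genes is not excluded. Cross-talk from a single tumour's library is argued against as well, since all 3 positions were among the 20 sites with the most reads in 51 of 51 resistant libraries. Sites within 1 Mb were no denser in resistant tumours (ratio 0.869, 95% interval 0.725 to 1.04), which gives no sign of mobile transposons inherited there. That ratio cannot exclude them. It pools all windows, that of Cradd lying on the donor chromosome, and its interval counts sites rather than tumours or mice. The 3 positions kept nearly fixed proportions, with an SD of the log2 ratio of 0.348 at most, as one DNA source carrying all 3 would give. The SD of log2 reads at one position was 2.5 or more, but that spread includes library depth, which a ratio within a library cancels. Ratios of other widely listed sites were not computed for comparison. DNA added during library preparation and inherited insertions, immobile or mobile, stay open.

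Nf1, a brake on RAS, and Kmt2c, a histone methyltransferase and breast tumour suppressor, were both hit in a larger share of resistant tumours. More sites per resistant tumour could have produced this. With the log number of sites as a covariate the odds ratio over sites of at least 10 reads was 6.95 for Nf1 (likelihood ratio p = 5.33e-05) and 3.84 for Kmt2c (p = 0.00287). That covariate counted every listed site of at least 10 reads, including shared positions that could not score in that tumour. The medians of that number were 493 in resistant and 459 in untreated tumours (permutation over mice, p = 0.698), which left little to adjust for. Numbers of sites that could score were not used as a covariate. Library series, as the title forms mark them, and treatment cannot be told apart, because no form held both groups, and the Nf1 odds ratio ran from 2.27 to 8.18 over the 4 pairings of forms while that of Kmt2c ran from 0.514 to 8.11. Mean shares per mouse over sites of at least 10 reads were 36.3% and 6.57% for Nf1 (permutation p = 0.00044) and 41.3% and 35.1% for Kmt2c (p = 0.560), which with 300 sites stood at 35.3% and 16.9% (p = 0.0591). With 100 sites they were 14% and 2.83% for Nf1 (permutation p = 0.1085) and 29% and 11.2% for Kmt2c (p = 0.0637). Selection for Nf1 insertions under BYL719 stays open as an untested hypothesis, since neither RAS activity nor loss of Nf1 function was measured here, and so does a difference between library series for either gene.

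Over all genes, 0 passed the threshold by the Fisher exact test, and 2 had an unadjusted p under 0.05. Of 100 groupings of the mice, the real one included, 100 gave as many genes past the threshold and the highest of the others was 0, which a real count of 0 fixes in advance, so that this test says nothing about chance. At the unadjusted threshold, 98 of the 100 had at least the 2 genes of the real grouping and the highest of the others had 13. The other groupings matched numbers of mice and not of tumours, with 58 to 89 tumours in the group that takes the place of the 51 resistant ones, so these counts are not like for like.

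The largest group differences in the authors' deposited table, such as those of Cradd, Sox6, Kalrn and Spred1, came from few insertions counted in many tumours. In 20 of the 20 genes with the largest difference, the group with the higher share had fewer insertions than hit tumours, compared with 42.9% of 326 other genes, which is consistent with one position being read in many tumours. With each position kept in 1 tumour and every site of at least 10 reads, 4 of these genes had an unadjusted Fisher p under 0.05 and 0 an adjusted one. Repeated independent insertion at a favoured position and transfer of reads between libraries were not tested apart. Nf1 was not among these 20, and its resistant share rested on 59 insertions over 29 tumours. Its untreated share rested on 23 insertions over 30 tumours, so fewer insertions than hit tumours.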

How the results depend on the processing

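All alternatives named here were planned beforehand, except those on the second deposited column, TTAA sites, tumours with under 100 own sites, the merged repeat library, the 3 shared positions, mean shares per mouse, mice with the wider sets, and adjustment over every gene region, which were chosen after the results were seen. Nf1 was hit in a larger share of resistant tumours under all 29 alternatives, with differences from 3.06 to 26.8 percentage points in shares of tumours, from 11.2 to 29.8 in mean shares per mouse, from 11.3 to 33.9 in shares of mice, an odds ratio of 3.99 with the number of sites as a covariate, and unadjusted p from 0.000164 to 0.472, and 19 alternatives left it on its side of the threshold. The other 10 took it past the threshold at an unadjusted p, namely 300 sites (21.1 percentage points by reads and by the second column, p = 0.000789 in both), every site of at least 10 reads (26.8), TgTum untreated tumours alone (10.1), Tgtumor resistant tumours alone (11.1), the mouse with the most hit tumours left out (10.6), the mouse as the unit with 300 sites (30.3) and at least 10 reads (33.9), and mean shares per mouse with the same sets (26.6 and 29.8). That mouse was an untreated one (exact p = 0.00957), chosen by the order of mouse names from a tie, and without the resistant mouse tied with it at 2 hit tumours the difference was 5.14 percentage points (exact p = 0.227). Leaving out each mouse in turn gave Nf1 differences from 5.14 to 10.6 percentage points with exact p from 0.00957 to 0.227. Of the 29 alternatives, labels permuted over mice, genes hit in at least 3 tumours and chromosome 10 left out could not change the Nf1 difference (8.57). All of these but the permutation could not change its unadjusted p either. With the smallest set, 50 sites per tumour, Nf1 was hit in 4 and 2 tumours, so its place past the threshold depended on the number of sites taken. The cause was not tested. With 100 sites and shared positions kept in every tumour, Nf1 was hit in 5 and 3 tumours (Fisher exact p = 0.130). The wider sets were not rerun with shared positions kept.

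The count of 0 genes that differed stayed at 0 under 21 of 25 alternatives, with 1 to 77 genes at an unadjusted p under 0.05 over all of them by the tests named. It was 1 with sites of at least 0.1% of reads (Ctnna3, -37.0 percentage points, adjusted p = 0.00175, from 0.00175 to 1 over its alternatives). Once the reads of the 3 shared positions were left out of the totals it was 0, with Ctnna3 at -25.2 percentage points (unadjusted p = 0.0039) and 603 rather than 534 genes tested, and the cause was not tested further. It was 1 (Kmt2c, higher) with Tgtumor tumours alone and 1 (Kmt2c) among genes hit in at least 10 tumours, where fewer genes were tested. It was 11 with shared positions kept in every tumour, among them Sox6, Cradd, Kalrn and Kmt2c. Kmt2c had differences from 6.12 to 27.9 percentage points under its alternatives with tumours or mean shares compared. Its difference in the share of mice hit reversed to -13.9 percentage points with at least 10 reads per site.

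Depth and design set further limits. The ratio of listed sites per tumour, 0.964, was 1.12 with at least 10 reads, 1.99 with at least 100 reads and 1.10 for sites in a single tumour, and the cause was not tested. With at least 100 reads the medians were 113 and 85, and 7 libraries of 0 such sites were counted as 1, without which the ratio was 1.67 (added later). Recurrent genes numbered 45 and 59 in resistant and untreated tumours, 24 and 30 with 50 sites, 107 and 180 with 300 sites, 225 and 389 with at least 10 reads, and 88 and 150 with all chromosomes kept. They fell to 8 and 4 with adjustment over every gene region rather than over genes hit in at least 3 tumours, a choice that selects on the tested quantity. In untreated tumours they also moved to 149 with sites of at least 0.1% of reads and to 105 with shared positions kept. Wider sets hold more sites and chromosome 10 holds the donor excess, by construction. Of the orientation tests 1 passed with at least 10 reads, and 0 passed between groups under 4 alternatives. No paired analysis was possible because no mouse gave tumours to both groups. The expectation from TTAA positions was not run, since it needs the genome sequence, and Nf1 has no value among genes hit in at least 10 tumours. The alternative that counts the repeat library apart equals the reported setting.

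Lists kept their direction and side of the threshold in 163 of 196 comparisons and named genes in 771 of 842. RAS-MAPK brakes passed with 300 sites (24.2 percentage points), and NOTCH, WNT and Hippo genes with Tgtumor tumours alone (21.2). The differences that changed sign, 31 for lists and 67 for named genes, follow, besides that of Kmt2c, as resistant minus untreated percentage points, and 0 of them passed its threshold. With 50 sites per tumour, these were Zfx (-0.334), Cntnap2 (0.730), Dmd (-1.40) and PI3K brakes (-2.46). With 300 sites, these were Mast4 (1.29), Rasa1 (8.57), Inpp4b (1.13), Ntrk3 (-0.334), cell cycle genes (-2.23), mammary factors (-4.34), markers of other cells (-0.334) and long genes (4.03). With every site of at least 10 reads, these were Ank3 (-4.80), 4930474G06Rik (4.15), Grm8 (0.459), Pcdh9 (8.64), Rasa1 (12), Ntrk3 (-2.96), Txnrd1 (3.59), Tgfbr2 (4.49), Smad2 (4.65), receptor kinases (-5.80), cell cycle genes (-9.28), TGF-beta genes (0.521), markers of other cells (-2.06) and long genes (6.15). With sites of at least 0.1% of reads, these were Ank3 (-0.271), Trps1 (-1.42), Ptprd (-7.55), Dmd (-2.23), Rasa1 (2.69), Kdm6a (-1.56), Ptprk (-2.90), Pard3b (-2.79), PI3K brakes (-4.19), cell cycle genes (-6.88), mammary factors (-6.53) and adhesion genes (-10.6). With shared positions kept in every tumour, this was PI3K brakes (-1.73). With 10 kb on each side of the gene, this was markers of other cells (-1.23). Against tgTum tumours alone, these were mammary factors (-0.891) and long genes (2.50). Against TgTum tumours alone, these were Dmd (-0.0321), Erbb4 (-0.675), PI3K brakes (-0.0321) and PI3K activators (2.6). With Tgtumor tumours alone, this was mammary factors (-4.80). With Mouse tumours alone, these were Trps1 (-12.6), Arfip1 (-4.39), Cntnap2 (5.05), Dmd (-1.20), Erbb4 (-5.32), Esr1 (5.85), Ptprk (-5.45), RAS-MAPK brakes (-3.32), PI3K brakes (-9.57), receptor kinases (-1.20), chromatin regulators (-6.65), NOTCH, WNT and Hippo genes (-3.46), adhesion genes (-0.532) and markers of other cells (-1.06). With the mouse as the unit, these were Trps1 (-6.96), Arfip1 (-2.78), Ptprd (-7.13), Runx1 (-1.39), Dmd (-10.4), Erbb4 (-5.39), Kdm6a (-1.04), Vgll4 (-5.39), Ptprk (-11.5) and Pard3b (-5.74). The cause of these changes was not tested.

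Under the alternatives chosen after the results were seen, further differences changed sign. Ranked by the second deposited column, this was Esr1 (3.82). With TTAA sites, this was Erbb4 (-0.334). With 0.1% of reads after the 3 shared positions were left out of the totals, these were Mast4 (0.563), Ptprd (-5.59), Rasa1 (4.65) and Kdm6a (-1.56). With 300 sites ranked by the second column, these were Mast4 (1.29), Rasa1 (7.51), Inpp4b (0.960), Ntrk3 (-0.334), Esr1 (0.918) and Vgll4 (-0.104). With sites at 2 or more in the second column, these were Runx1 (-2.63), Cntnap2 (2.52), Dmd (-2.63), Rasa1 (0.730), Inpp4b (3.59) and Esr1 (5.05). With sites at 3 or more in it, these were Runx1 (-2.29), Dmd (-0.334), Esr1 (0.563), Vgll4 (-1.56) and Ptprk (-0.501). Without tumours of under 100 own sites, this was mammary factors (-0.523). With mean shares per mouse, these were PI3K brakes (-2.54) and PI3K activators (0.818). The cause was not tested here either.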

Other observations

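The tests of clustering within tumours for Nf1, Kmt2c, Trps1 and Fbxw7 and the test of positions shared by one mouse's tumours were chosen after the result was seen, and both were changed once after their first value. The values without one tumour, one mouse or the 3 shared positions were also added afterwards. The tests of clustering in other genes and of Nf1 with Kmt2c in the same tumours were chosen before.

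Rasa1, which switches RAS off as Nf1 does and was chosen here after its values were seen, was hit in 11 resistant tumours (21.6%, 95% interval 11.3 to 35.3) and 9 untreated tumours (9.57%, 4.47 to 17.4) with every site of at least 10 reads (Fisher exact p = 0.0750, adjusted p = 1).

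Some resistant tumours held several sites of the same gene. Sites of a gene were assigned at random and independently to tumours, in proportion to each tumour's number of sites. With 100 sites per tumour and sites of a tumour within 10 bp counted once, the 14 Nf1 sites lay in 6 tumours against 12.3 by random assignment (one-sided p = 1e-05, the smallest that the assignments can give). The 24 Kmt2c sites lay in 14 against 19.1 (p = 0.00272), the 82 Trps1 sites in 32 against 39.9 (p = 0.00052), and the 14 Fbxw7 sites in 8 against 12.3 (p = 0.00093). The Nf1 clustering rested on resistant tumour 10, which held 8 of the sites, since the other 6 sites lay in 5 tumours against 5.69 (random assignment p = 0.279). Without the tumour with the most sites, Kmt2c (p = 0.00928), Trps1 (p = 0.00146) and Fbxw7 (p = 0.0385) still clustered by the same random assignment. In untreated tumours the 84 Trps1 sites lay in 53 tumours against 54.5 (p = 0.365), and a difference between the groups in clustering was not tested. Several insertions per tumour might reflect independent clones with insertions in the gene, or repeated insertion near one place, and the latter could act in any gene. Of 14 other genes with at least 5 sites in resistant tumours, 28.6% also clustered at an unadjusted random assignment p under 0.05 (4.08% of 49 in untreated tumours). Several sites in a tumour help a gene to reach 5 sites, so this choice of genes favours clustering.

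Across resistant tumours, hits in Nf1 and Kmt2c did not avoid each other. A tumour can hold several clones, so this count cannot tell whether the genes exclude each other within a clone. With every site of at least 10 reads, 15 resistant tumours carried both, 3 Nf1 alone, 9 Kmt2c alone and 24 neither (odds ratio 12.5, 95% interval 2.69 to 83.8, Fisher exact p = 0.000283). With the log number of sites as a covariate the odds ratio was 4.62 (likelihood ratio p = 0.0931), so that tumours with many sites may account for part of the overlap.

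Tumours of one mouse shared slightly more top sites than the mean of all pairs of their title form, by 0.469 percentage points over 212 pairs (permutation p = 0.0057). Cells in common and transfer of reads between libraries were not tested apart as sources of this sharing. The Tgtumor form ran the other way, with 1.38% shared by same-mouse pairs and 1.49% by other pairs. The median shared percent was 0 for same-mouse pairs of both untreated forms. Pairs that shared over 10% numbered 4 from one mouse and 4 from different mice in the TgTum form, and 1 and 1 in the tgTum form. They numbered 0 and 3 in the Tgtumor form and 1 and 6 in the Mouse form. The value first computed, with title forms pooled and the 3 shared positions kept, was -0.0251 (p = 0.997).

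Reads at sites outside TTAA made up a median of 2.07% of a resistant library and 4.71% of an untreated library (permutation over mice, p = 1e-05, the smallest that the permutations can give). The 3 positions lie at TTAA and carry resistant reads alone, which lowers the resistant percent by construction. Without their reads the medians were 3.59% and 4.71%, and no difference was detectable (permutation p = 0.257).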
